A study of Rattus norvegicus with 23 samples.

How the data were processed

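Polyadenylated RNA from the femora of female Wistar rats was sequenced as bulk libraries, 1 per labelled sample. The 23 libraries fell into 5 groups by their titles, namely healthy control (n = 4), MetOP saline (n = 5), MetOP with semaglutide (n = 5), MetOP with PYY3-36 (n = 4, called PYY here) and MetOP with both drugs (n = 5). MetOP, the metabolic osteoporosis model named in the labels, was induced with a high-fat diet and L-NAME, an inhibitor of nitric oxide synthase. Semaglutide activates the GLP-1 receptor, and PYY3-36 is a gut peptide that acts mainly through the neuropeptide Y receptor Npy2r. The treatment labels of the 4 PYY libraries differ in the last number of the peptide name (PYY3-36, PYY3-37, PYY3-38 and PYY3-39), so that they all received PYY3-36 rests on their shared title. Titles of the MetOP libraries carry a further abbreviation (lfd) after that of the high-fat diet, which the labels do not explain, so the diet at the time of sampling is not known. All libraries carry the same batch label. Nothing in the labels states that the libraries of a group came from separate animals, so p-values measure the spread between these samples. Libraries are named by group and by their column in the deposited tables.

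Raw counts per Ensembl gene were deposited by the authors, one column per library, for 30562 genes. The deposited FPKM values were made by the authors from those counts with a depth per library that is a fixed multiple of its DESeq2 size factor, a relation found in the values themselves. They were used only to check the counts, and the implied depth of 26.39 M per unit of size factor held for every library. The genome build was mRatBN7.2 and DESeq2 1.42.0 was used, per the submitters' processing notes. The aligner and the counter are not given in the sources used here. The labels' protocol describes library preparation both with and without strand marking and does not say which was used, so counts of overlapping and antisense genes are uncertain, as are those of pseudogenes and near-identical paralogs. No genome sequence was used here, and coordinates are those of the deposited table.

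Totals ran from 19.25 to 40.65 M counts per library (M as in counts per M), with a median of 25.9 M. The 37 mitochondrially encoded genes took 46.1 to 83.9% of the counts of a library, which left 4.28 to 16.1 M counts for all other genes. Of the 30562 genes, 10661 had no count in any library. A count of 0 allows up to 3 counts, or 0.0738 to 0.156 counts per M (CPM) of the library total, before any scaling, depending on the library. Such floors and the 95% intervals cover counting error only, because reads carried no molecular identifiers. In the 42 pairs of libraries within groups, correlations of log2 CPM ran from 0.666 to 0.937 and the lowest chi-square per degree of freedom was 31.96, so no pair agreed within sampling noise and each library counted as 1 sample.

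Differences were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (TMM normalization, filterByExpr by group, robust dispersion). All 23 libraries were fitted together with 1 mean per group and 18 residual degrees of freedom. This left 15271 tested genes, a common biological coefficient of variation of 69.9% and a median gene-wise one of 52.2%. The 8 comparisons were MetOP saline versus healthy control, each drug group versus MetOP saline, the 3 differences between drug groups, and the interaction of semaglutide and PYY, the departure of the combination from additive log2 effects. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the 15271 genes. Levels are CPM scaled by the TMM factors, as mean ± SD, and fold changes are log2, given as value ± standard error (SE) where they stand in parentheses after a gene.

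Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01, adjusted over 34 lists), with an estimated correlation, and with fry, whose directional test asks whether the genes of a list move one way on balance and whose mixed test asks for changes in either direction. The 34 lists held 705 entries, of which 683 matched by symbol, 4 by an older symbol and 18 did not match, and 652 were tested. They covered cells of bone and marrow (osteoblast, osteocyte, osteoclast, chondrocyte, marrow stroma, adipocyte, fibroblast, endothelial, erythroid, megakaryocyte, neutrophil, mast and basophil, macrophage, B, plasma, T and NK cells) and skeletal muscle. The others covered Wnt signalling, the IGF axis, peptide receptors, nitric oxide and vascular tone, inflammation, interferon response, fatty acid oxidation and synthesis, cholesterol synthesis, oxidative phosphorylation, glycolysis, hypoxia, unfolded protein response, cell cycle, glucocorticoid response, immediate early and heat shock genes, and the circadian clock. A list level is the mean log2 CPM of its tested genes in a library, with a prior count of 2.

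Groups, comparisons, lists, the first set of other fits and the rule for named genes were fixed before the data were examined. The rule named up to 8 rising and 8 falling genes that passed with a mean log2 CPM of at least 0 and a gene symbol, or, where none passed, the 3 higher and the 3 lower genes of smallest p. It added up to 4 passing members of each called list, or else the 2 members of smallest p, and 16 genes in every comparison (Col1a1, Bglap, Alpl, Sp7, Runx2, Sost, Dmp1, Acp5, Ctsk, Tnfsf11, Tnfrsf11b, Adipoq, Pparg, Glp1r, Npy1r and Npy2r). Genes outside that rule are said to have been chosen after their values were seen.

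Percentages of counts and numbers of genes at 0 were compared between groups with exact two-sided permutation tests in Python 3.11.15 with scipy 1.17.1, 28 tests in all. All 34 list levels were compared in the same way in the 7 comparisons between 2 groups, tests chosen after the list tests were seen. Correlations over libraries used 100000 permutations and were chosen after the list tests.

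These other fits were DESeq2 1.42.0, limma voom with sample weights, RLE normalization, no filter, a filter of 1 CPM in 4 libraries, an absolute log2 fold change of at least 1, a fit of the compared groups alone, the skeletal muscle level as a covariate, leaving out 3 libraries whose label numbers lie apart from their group (MetOP saline A265, combination A318 and A320), and leaving out each library in turn. Added after the data were seen were fits without the mitochondrially encoded genes, without the 2 libraries with most Y-linked counts, without the 4 libraries over 80% mitochondrial counts, and with 2 surrogate variables (sva 3.50.0).

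Scripts were tested on simulated data drawn from the 15271 genes for semaglutide versus MetOP saline, with 50 genes changed at each fold. The edgeR test recovered 3 genes at 2-fold, 17 at 4-fold, 25 at 8-fold and 33 at 16-fold, with 1 false call among 79. DESeq2 recovered 14, 25, 31 and 37, with 46 false calls among 153, and limma voom 4, 16, 25 and 29, with 5 false among 79. In a second simulation false calls were 3 of 95 with edgeR, 33 of 144 with DESeq2 and 3 of 87 with limma voom. With no gene changed, DESeq2 made 6 false calls in 1 of 2 simulations and edgeR and limma voom 0, so DESeq2 counts of that size carry little weight. Genes were drawn independently in all simulations, without shared differences in makeup between libraries. The low numbers of false calls with edgeR and limma voom therefore need not hold for the real libraries. A B-cell list doubled in the simulation was called by camera in 1 of 2 simulated data sets. Splits of the samples numbered 100 per comparison, the real grouping included, and unchanged groups sharing the MetOP saline libraries were simulated 20 times.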

Results

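Femoral RNA was measured in 23 libraries from female Wistar rats, 4 from healthy controls, 5 from MetOP rats given saline, 5 given semaglutide, 4 given PYY and 5 given both drugs. Values after genes in parentheses are log2 fold changes ± SE. Library totals lay between 19.25 M counts (M as in counts per M, CPM) (combination A248) and 40.65 M (combination A253). Mitochondrially encoded transcripts took 68.16% ± 10.98 (SD, n = 4) of the counts in healthy controls and 75.25% ± 7.84 (n = 5) in MetOP saline. They took 61.4% ± 5.31 (n = 5) with semaglutide, 63.6% ± 7.82 (n = 4) with PYY and 67.05% ± 13.5 (n = 5) with both. Skeletal muscle genes took between 1.26% (combination A320) and 26.4% (combination A251) of the remaining counts, so the femora carried variable amounts of muscle RNA. None of the 28 exact permutation tests of library makeup passed after adjustment (smallest adjusted p = 0.333), which groups of this size leave little room for.

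**Figure D1:**
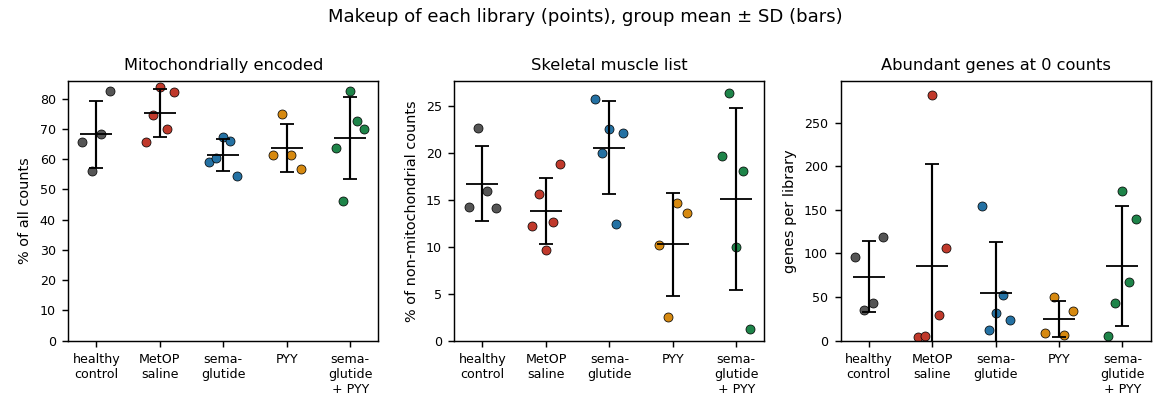
Makeup of the 23 libraries by group, as mitochondrially encoded counts in percent of all counts, skeletal muscle genes in percent of non-mitochondrial counts, and the number of 10816 abundant genes without a count. Points are libraries and bars are the group mean ± SD, drawn down to 0 at most; the lowest muscle share is 1.26% and the highest number of genes at 0 is 282.

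The receptors addressed by the drugs were scarce in these femora. Glp1r, the receptor of semaglutide (chromosome 20, 8972004 to 9010241), had 0 counts in all 23 libraries. This allows at most 0.0738 to 0.156 CPM per library, taken over all counts and not scaled by the TMM factors as the levels below are. Npy2r, the main receptor of PYY3-36 (chromosome 2, 167903879 to 167905024), had 7 counts in PYY A216 and 0 in the others. Npy1r, a receptor of neuropeptide Y and full-length PYY (chromosome 16, 23037789 to 23046759), was counted in every library, at 2.25 ± 0.36 CPM in healthy controls (n = 4), 4.27 ± 2.02 in MetOP saline (n = 5) and 10.15 ± 8.43 with PYY (n = 4). Its log2 fold change for PYY versus MetOP saline was 1.25 (SE 0.59, edgeR adjusted p = 1.0) and did not pass.

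Across the comparisons, camera called gene lists on the preset correlation, but none of those calls held with an estimated correlation or with the directional test of fry. The mixed test of fry, which asks for changes in either direction, called 5 lists in semaglutide versus PYY (fibroblast, endothelial, nitric oxide, Wnt signalling and hypoxia, adjusted p = 0.0373 each) and 0 in the other comparisons. Exact permutation tests of all 34 list levels in the 7 comparisons between 2 groups gave, in 21 cases, an unadjusted p under 0.05, and none passed after adjustment (smallest adjusted p = 0.521). With 5 and 5 libraries no exact p can lie below 0.00794, so that adjustment could hardly be passed and decides nothing about the lists. Directions of lists below are those of the preset test, with the adjusted p of the estimated correlation beside them. The smallest adjusted p of the directional fry test in any comparison was 0.0607, in semaglutide versus PYY. In no called list did a member pass over all genes tested, so each list below counts 0 members that rose and 0 that fell on that criterion.

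MetOP saline versus healthy control sets the disease model against healthy bone, with the diet at the time of sampling not stated. Transcripts of the bone-forming osteoblasts showed little difference, with Col1a1, the main collagen chain of bone matrix (chromosome 10, 79883622 to 79900624), at 1100 ± 1070 CPM in MetOP saline (n = 5) and 1307 ± 1375 in controls (n = 4). The osteocalcin gene Bglap had a log2 fold change of -0.58 (SE 0.66) and the osteocyte gene Sost, an inhibitor of bone formation, one of -0.64 (SE 1.02). Osteoclast genes, which serve bone resorption, were higher in 18 of 20 (median log2 fold change 0.45, Calcr 2.32 ± 1.46, Itgb3 1.70 ± 0.98). Cartilage genes were higher in 16 of 17 (median 1.21, Col10a1 of hypertrophic cartilage 2.85 ± 2.05, Acan 1.72 ± 1.76). Control A392 alone, with a cartilage level of 5.815 log2 CPM against -2.077 to -0.753 in the other 3 controls, made the difference in mean level (2.889) smaller. Genes of nitric oxide and vascular tone were higher in 14 of 22 (median 0.38), including endothelial nitric oxide synthase Nos3 at 10.5 ± 3.49 CPM against 5.19 ± 3.01, and Ddah1, which degrades endogenous inhibitors of that enzyme, at 5.24 ± 4.71 against 1.38 ± 0.51. Macrophage genes were higher in 12 of 15 (median 0.48, Mrc1 1.22 ± 0.54, Spic 1.36 ± 0.76), and immediate early and heat shock genes in 14 of 22 (median 0.13, Fosl2 2.19 ± 0.66, Junb 1.16 ± 0.36).

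Oxidative phosphorylation genes were lower in 37 of 38 in MetOP saline (median -0.50, Ndufb8 -0.73 ± 0.40). Fatty acid oxidation genes were lower in 22 of 26 (median -0.38, Decr1 -0.68 ± 0.51, Hadhb -0.66 ± 0.51). Skeletal muscle genes were lower in 26 of 26 (median -0.45, Acta1 -0.82 ± 0.74, Mb -0.73 ± 0.76). Muscle genes took 13.8% of non-mitochondrial counts in MetOP saline and 16.7% in controls (exact permutation p = 0.286, n = 5 and 4). Single genes of smallest p, none of which passed, were the endocytosis gene Fcho2 (2.66 ± 1.08 CPM in controls, 10.7 ± 3.56 in MetOP saline), Aff1 (log2 fold change 1.95 ± 0.37) and Trim44 (1.48 ± 0.28), each at an adjusted p of 0.119. On the lower side stood Gsta6 (-1.34 ± 0.35) and the RNA demethylase gene Fto (-0.92 ± 0.26).

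In this comparison of MetOP saline with healthy control, camera called 8 lists. The adjusted p was 1.06e-05 for oxidative phosphorylation, 0.00132 for chondrocyte, 0.0159 for fatty acid oxidation, 0.017 for skeletal muscle. It was 0.0261 for macrophage and for immediate early genes, 0.0294 for osteoclast and 0.0378 for nitric oxide. Each had an adjusted p = 0.995 with an estimated correlation, and 3 immediate early genes rose adjusted over the list alone, against 0 members of the other 7 lists. The edgeR test called 0 of 15271 genes, with 1000 at an unadjusted p under 0.05 against 764 from chance alone, while DESeq2 called 51 and limma voom 0. Without control A389 the number of called lists went from 8 to 0, without MetOP saline A229 to 3, without MetOP saline A224 to 5, and with the muscle level as a covariate to 3. The median of the nitric oxide list, of which 2 members had no count in 1 of the groups, was 0.38 with these at their bound.

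Semaglutide versus MetOP saline asks what semaglutide did in the diseased skeleton. Transcripts of bone-forming, bone-resorbing and cartilage cells were lower with semaglutide. Ibsp, a mineral-binding protein of bone matrix (chromosome 14, 5439829 to 5452693), was at 17.5 ± 11.3 CPM (n = 5) against 205 ± 164 (n = 5), and Col1a1 at 141 ± 88.2 against 1100 ± 1070 (log2 fold change -2.97 ± 0.87). Osteoclast genes were lower too, with the acid phosphatase gene Acp5 (chromosome 8, 20663985 to 20667929) at 6.84 ± 5.83 against 84.6 ± 74.1 CPM and the collagen-degrading protease gene Ctsk (chromosome 2, 183058569 to 183069550) at 15.8 ± 9.58 against 168 ± 130. None of these genes passed (adjusted p = 0.371 for each).

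In semaglutide versus MetOP saline, 24 of 25 osteoblast genes were lower (median log2 fold change -2.05), among them the collagenase gene Mmp13 (-3.53 ± 0.92), the alkaline phosphatase gene Alpl (-2.42 ± 0.70), the osteoblast transcription factors Runx2 (-2.22 ± 0.69) and Sp7 (-2.05 ± 0.77) and Bglap (-1.92 ± 0.65). Of these 25, 15 fell adjusted over the list alone. The list level was 2.30 ± 0.61 log2 CPM with semaglutide and 4.19 ± 1.14 with saline (exact permutation p = 0.0159, adjusted 0.521, n = 5 and 5), and 4 of 5 semaglutide libraries lay below the lowest saline library. All 17 chondrocyte genes were lower (median -5.86, also with the 1 gene without counts at its bound, Col11a2 -4.63 ± 1.29, Ucma -6.29 ± 1.94), and 17 fell adjusted over the list alone. In the osteoclast list 19 of 20 were lower (median -1.27, Ckb -2.20 ± 0.54), and 4 fell adjusted over the list alone. The osteocyte gene Dmp1 had a log2 fold change of -2.24 (SE 0.53). Sost (-0.38 ± 0.97) and the osteoclast-activating ligand gene Tnfsf11 (-0.30 ± 1.34) had SEs larger than their changes, so a change either way is not excluded. The decoy receptor gene of that ligand, Tnfrsf11b, was at -3.18 (SE 1.22).

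Marrow and connective tissue lists were also lower in semaglutide versus MetOP saline. Cell cycle genes were lower in 34 of 35 (median -1.46, the S-phase genes Ccne2 -1.89 ± 0.57 and Mcm4 -1.31 ± 0.41). Erythroid genes were lower in 20 of 21 (median -1.58, Gata1 -1.58 ± 0.60, Tfrc -0.94 ± 0.31). Neutrophil genes were lower in 13 of 19 (median -0.41, Ctsg -1.02 ± 0.81, S100a8 -0.87 ± 0.72). In neutrophil level 4 of 5 semaglutide libraries lay below every saline library and 1 lay above (exact permutation p = 0.222, adjusted 0.699, n = 5 and 5). Megakaryocyte genes were lower in 11 of 13 (median -1.01, Clec1b -1.64 ± 0.63, F2rl2 -1.93 ± 1.19, exact permutation p of list level 0.214, adjusted 0.699). Macrophage genes were lower in 14 of 15 (median -1.24, Cd68 -2.30 ± 0.71, Mrc1 -1.61 ± 0.51) and fibroblast genes in 15 of 17 (median -0.90, Col6a3 -2.19 ± 0.57, Col6a1 -1.93 ± 0.54), of which 2 and 4 fell adjusted over the list alone. Haemoglobin genes took 1.80% of non-mitochondrial counts against 5.82% (exact permutation p = 0.0476, adjusted 0.333, n = 5 and 5). In the other direction, all 38 oxidative phosphorylation genes (median 0.63, Sdha 0.82 ± 0.40, Ndufv1 0.80 ± 0.40), 23 of 26 fatty acid oxidation genes (median 0.96, Acaa2 1.15 ± 0.49, Eci1 1.48 ± 0.63) and all 26 skeletal muscle genes (median 0.82, Acta1 1.23 ± 0.71, Xirp2 0.91 ± 0.56) were higher. The difference in mean muscle level was 0.621 (exact permutation p = 0.27, adjusted 0.747, n = 5 and 5). Semaglutide A242 alone, with a muscle level of 8.85 log2 CPM against 10.864 to 11.351 in the other semaglutide libraries, made it smaller. Muscle genes took 20.5% of non-mitochondrial counts with semaglutide and 13.8% with saline (exact permutation p = 0.0397, adjusted 0.333), and mitochondrially encoded genes 61.4% against 75.25% of all counts (p = 0.0238, adjusted 0.333, exact permutation tests with n = 5 and 5). The oxidative phosphorylation level was 6.92 log2 CPM with semaglutide and 6.26 with saline, with 5 of 5 semaglutide libraries above every saline library (exact permutation p = 0.00794, adjusted 0.521, n = 5 and 5). The adipocyte genes Adipoq (-0.72 ± 0.67) and Pparg (-1.47 ± 0.49) did not pass.

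Camera called 12 lists for semaglutide versus MetOP saline, with adjusted p-values of 3.77e-17 for cell cycle, 6.15e-14 for osteoblast, 8.51e-11 for erythroid, 1.85e-09 for chondrocyte, 8.27e-09 for oxidative phosphorylation. They were 1.51e-07 for osteoclast, 2.36e-07 for macrophage, 3.9e-07 for fatty acid oxidation, 1.71e-05 for fibroblast, 0.000686 for skeletal muscle, 0.00697 for neutrophil and 0.0245 for megakaryocyte. Cell cycle, osteoblast, erythroid, chondrocyte, osteoclast, macrophage and fibroblast lists each had an adjusted p = 0.461 with an estimated correlation. With it the value was 0.481 for fatty acid oxidation, 0.564 for oxidative phosphorylation and 0.596 for muscle, neutrophil and megakaryocyte genes. No member of the cell cycle, erythroid, oxidative phosphorylation, fatty acid oxidation, muscle, neutrophil or megakaryocyte lists passed when adjusted over the list alone. Gene by gene, edgeR called 0, with 1744 at an unadjusted p under 0.05 (638 higher and 1106 lower), DESeq2 called 92 and limma voom 184. Smallest p-values belonged to Cenpm, a centromere protein gene with 1 count in 1 of 5 semaglutide libraries against 4 to 115 in each of the other 18 libraries (count ratio to MetOP saline 0.00491, 95% counting interval 0.000124 to 0.0277), and to Ddr2, a collagen receptor gene (log2 fold change -1.68 ± 0.31), both at an adjusted p of 0.0913. Bet1 was next on the lower side (-0.93 ± 0.22), and Eif4g3 (0.82 ± 0.19), Bag6 (0.81 ± 0.21) and Srf (0.82 ± 0.21) on the higher side. With 2 surrogate variables the osteoblast median was -0.50, and the oxidative phosphorylation and muscle lists were called in the opposite direction (medians -0.27 and -0.23).

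**Figure D2:**
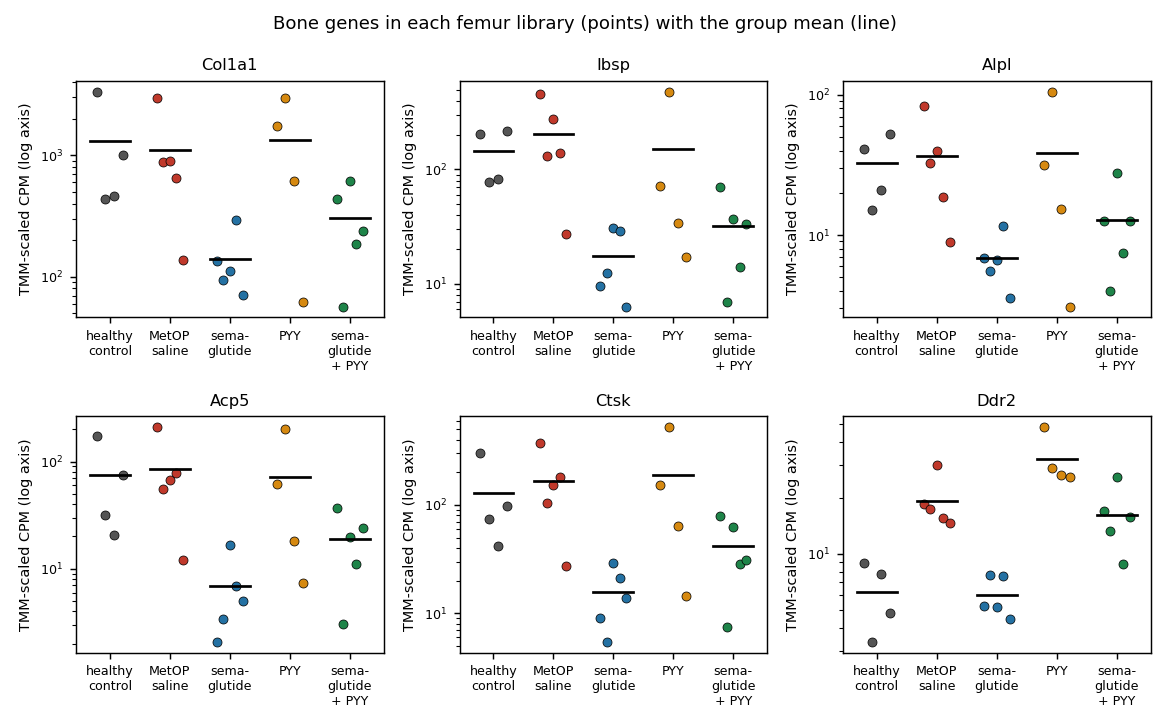
Levels of the matrix genes Col1a1 and Ibsp, the mineralization gene Alpl, the osteoclast genes Acp5 and Ctsk and the collagen receptor gene Ddr2 in the 23 libraries, as TMM-scaled CPM on a log axis. Points are libraries and lines are group means; Ibsp averages 17.5 CPM with semaglutide and 205 CPM with saline, and Ddr2 lies between 4.47 and 7.67 CPM with semaglutide and between 25.95 and 48.3 CPM with PYY.

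PYY versus MetOP saline asks what PYY3-36 did in the diseased skeleton. Connective tissue and vessel genes were higher with PYY. Fbn1, which encodes the microfibril protein fibrillin-1 (chromosome 3, 112554925 to 112750889), was at 78.5 ± 99.5 CPM with PYY (n = 4) against 10.5 ± 2.38 (n = 5), and PYY A215 alone reached 225.8 CPM. All 17 fibroblast genes were higher (median log2 fold change 1.19, Fbn1 2.91 ± 0.58, Clec3b 2.57 ± 0.80), as were 16 of 18 endothelial genes (median 0.76, Ptprb 1.12 ± 0.30, Robo4 1.11 ± 0.36). The same held for 18 of 22 genes of nitric oxide and vascular tone (median 0.44, also with 1 gene at its bound, Ace 1.23 ± 0.38, Cav1 0.94 ± 0.30). Interferon response genes were higher in 18 of 23 (median 0.26, Rtp4 1.54 ± 0.60, Ifi44 0.81 ± 0.37). Exact permutation tests of list level gave p = 0.413 (adjusted 0.833) for fibroblast and 0.0635 (0.521) for endothelial genes, n = 4 and 5. The p was 0.0476 (0.521) for nitric oxide and for interferon response genes. In fibroblast level 1 of 4 PYY libraries lay below every saline library and 3 lay above. Neither the osteoblast nor the osteoclast list was called with PYY. Col1a1 (0.29 ± 0.86), Bglap (0.11 ± 0.66), Alpl (0.09 ± 0.70), Runx2 (-0.18 ± 0.70), Sp7 (0.02 ± 0.78), Acp5 (-0.23 ± 0.85), Ctsk (0.16 ± 0.81) and Sost (0.11 ± 1.03) had SEs larger than their changes.

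Blood and muscle genes were lower in PYY versus MetOP saline. Neutrophil genes were lower in 18 of 19 (median -1.30, Cxcr2 -2.33 ± 1.15, the antimicrobial peptide gene Camp -1.87 ± 0.94). Megakaryocyte genes were lower in 12 of 13 (median -1.40, Treml1 -3.41 ± 1.16, with Vwf at 1.00 ± 0.36). Erythroid genes were lower in 21 of 21 (median -0.81, Tfrc -0.64 ± 0.33, Sptb -0.62 ± 0.32). Cell cycle genes were lower in 33 of 35 (median -0.65, Mcm4 -0.85 ± 0.43, Rrm1 -0.64 ± 0.32). Skeletal muscle genes were lower in 22 of 26 (median -0.59, Eno3 -1.05 ± 0.75, Tnnc2 -1.09 ± 0.78). Oxidative phosphorylation genes were lower in 37 of 38 (median -0.37, Uqcrh -0.51 ± 0.35, Cox5a -0.60 ± 0.44). Glycolysis genes were lower in 15 of 22 (median -0.41, Gpi -0.72 ± 0.49, with the glucose transporter gene Slc2a1 at 1.41 ± 0.63). Exact permutation tests of these list levels gave p = 0.0317 for neutrophil, 0.0635 for muscle, 0.0794 for glycolysis and 0.111 for megakaryocyte genes. The p was 0.254 for erythroid, 0.317 for cell cycle and 0.333 for oxidative phosphorylation genes, and none passed after adjustment. Muscle genes took 10.25% of non-mitochondrial counts with PYY and 13.8% with saline (exact permutation p = 0.333, n = 4 and 5). PYY A216, at 2.51%, made this difference larger, and the group medians were 11.93% and 12.65%. Emp2 (1.59 ± 0.32, adjusted p = 0.396), the Hippo kinase gene Lats2 (0.91 ± 0.22), the ribosomal RNA genes Rn18s (-1.29 ± 0.30) and Rn5-8s (-3.80 ± 1.03) and Rpl37l1 (-0.78 ± 0.22) had the smallest p-values besides Fbn1, and none passed.

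Camera called 11 lists for PYY versus MetOP saline. The adjusted p was 1.97e-10 for endothelial, 1.85e-07 for skeletal muscle, 3.08e-07 for neutrophil and for oxidative phosphorylation, 9.82e-07 for erythroid. It was 1.75e-06 for cell cycle, 3.4e-06 for fibroblast, 0.00132 for megakaryocyte, 0.00162 for nitric oxide, 0.00626 for glycolysis and 0.0103 for interferon response. These became an adjusted p = 0.457 with an estimated correlation for endothelial genes, 0.564 for nitric oxide genes, 0.636 for fibroblast and glycolysis genes, and 0.649 or 0.681 for the rest. Adjusted over the list alone, 4 endothelial, 4 fibroblast and 2 nitric oxide genes rose and no member of the other 8 lists passed. By edgeR, 0 genes were called (740 at an unadjusted p under 0.05, 764 expected), DESeq2 called 5 and limma voom 39; without PYY A220 edgeR called 1, and without PYY A216 the lists rose from 11 to 17.

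Semaglutide plus PYY versus MetOP saline asks what the combination did. Most bone and cartilage genes were again lower, though libraries of the groups overlapped in list level. Exact permutation tests of list level gave p = 0.167 (adjusted 0.652) for osteoblast, 0.198 (0.693) for chondrocyte and 0.0556 (0.521) for osteoclast genes. In the osteoblast and osteoclast lists 1 of 5 combination libraries lay below the lowest saline library, and in the chondrocyte list 3 of 5. Osteoblast genes were lower in 23 of 25 (median log2 fold change -1.05), with Ibsp at 32.3 ± 24.8 CPM (n = 5) against 205 ± 164 (n = 5) and the matrix phosphoprotein gene Spp1 at -2.32 (SE 0.83). Chondrocyte genes were lower in 17 of 17 (median -3.06, Comp -3.43 ± 1.44, Col11a2 -2.59 ± 1.17). Osteoclast genes were lower in 19 of 20 (median -0.98, also with 1 gene at its bound, Acp5 -2.17 ± 0.84, Ctsk -2.01 ± 0.79). Erythroid genes were lower in 21 of 21 (median -0.35, Tfrc -0.54 ± 0.31, Ermap -0.82 ± 0.88). Cell cycle genes were lower in 28 of 35 (median -0.27, Cenpf -0.90 ± 0.67, Bub1 -0.54 ± 0.42). Macrophage genes were lower in 11 of 15 (median -0.27, C1qa -0.93 ± 0.43, Csf1r -0.75 ± 0.71). Col1a1 (-1.85 ± 0.84) and Alpl (-1.50 ± 0.68) did not pass, nor did Bglap (-0.55 ± 0.63), Dmp1 (-0.77 ± 0.51), Adipoq (-0.96 ± 0.67) or Npy1r (-0.02 ± 0.56).

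Smallest p-values in semaglutide plus PYY versus MetOP saline belonged to the transcription factor gene Dach1 (-2.11 ± 0.50), Lats2 (0.84 ± 0.21), Nek3 (1.65 ± 0.47), Apc of the Wnt pathway (-0.69 ± 0.21), Cmtr2 (-1.42 ± 0.44) and Eif2s3y, and none passed. Eif2s3y, a gene on the Y chromosome, had 0 counts in all MetOP saline libraries and 724, 58, 0, 356 and 24 in combination A248, A251, A253, A318 and A320, at least 358-fold higher over the group. The labels give all animals as female. Camera called 6 lists, at adjusted p-values of 1.44e-09 for osteoblast, 1.26e-07 for chondrocyte, 1.69e-07 for osteoclast, 0.00115 for erythroid, 0.00134 for cell cycle and 0.0499 for macrophage. They became an adjusted p = 0.773 with an estimated correlation for the osteoblast and osteoclast lists, 0.887 for the chondrocyte list and 0.997 for the others, and 0 members of the 6 lists passed adjusted over the list alone. The edgeR test called 0 genes (468 at an unadjusted p under 0.05), DESeq2 called 5 and limma voom 0. Without combination A320 the lists went from 6 to 15, and without combination A248 or MetOP saline A229 to 3.

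**Figure D3:**
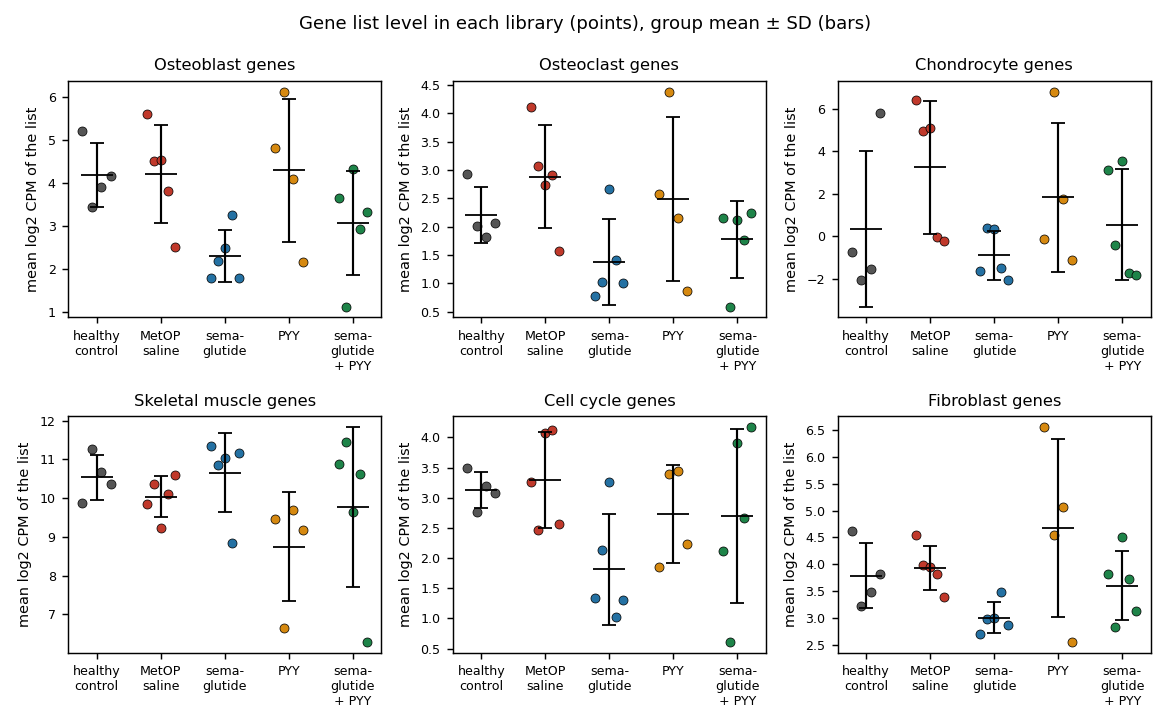
Mean log2 CPM of the osteoblast, osteoclast, chondrocyte, skeletal muscle, cell cycle and fibroblast lists in each of the 23 libraries. Points are libraries and bars are the group mean ± SD; the osteoblast level is 2.30 ± 0.61 with semaglutide and 4.19 ± 1.14 with saline, and the lowest muscle level, 6.29, is that of combination A320.

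Semaglutide plus PYY versus semaglutide asks what PYY added. Lists called lower with semaglutide alone were higher in the combination, except the osteoclast list, which was not called (median 0.26, exact permutation p = 0.389, n = 5 and 5). Both comparisons use the same 5 semaglutide libraries with opposite sign, so a chance low in these alone would give such a reversal. No exact permutation test of list level gave an unadjusted p under 0.05 here (smallest 0.0873, fibroblast). The p was 0.23 for osteoblast, 0.333 for chondrocyte, 0.381 for erythroid, 0.603 for neutrophil and 0.524 for muscle genes. Osteoblast genes were higher in 24 of 25 (median log2 fold change 1.02, Bglap at 33.6 ± 26.3 CPM against 13.0 ± 9.08, n = 5 and 5, Dlx5 1.45 ± 0.74). Chondrocyte genes were higher in 17 of 17 (median 2.80, or 2.74 with 1 gene at its bound, Ucma 4.07 ± 1.81, Acan 3.31 ± 1.77). Fibroblast genes were higher in 17 of 17 (median 0.82, Pi16 2.10 ± 0.58, Ogn 0.88 ± 0.38). Cell cycle genes were higher in 35 of 35 (median 1.18, Mcm4 1.09 ± 0.40, Rrm1 0.78 ± 0.30). Erythroid genes were higher in 20 of 21 (median 1.22, Gata1 1.33 ± 0.60, Hemgn 1.49 ± 0.69). Macrophage genes were higher in 15 of 15 (median 1.11, Clec10a 1.92 ± 0.72, Cd68 1.76 ± 0.70). Neutrophil genes were higher in 18 of 19 (median 0.94, Ceacam1 1.01 ± 0.62, Lcn2 1.26 ± 0.87). The same held for 11 of 13 megakaryocyte genes (median 0.95, F2rl2 2.326 ± 1.196, Clec1b 1.14 ± 0.62), 11 of 13 marrow stroma genes (median 0.63, Foxc1 2.77 ± 1.41, with Esm1 at -1.24 ± 0.61) and 8 of 8 plasma cell genes (median 0.61, Sdc1 1.53 ± 0.59, Cd38 0.83 ± 0.45). Oxidative phosphorylation genes were lower in 37 of 38 (median -0.43, Cycs -0.91 ± 0.57, Ndufs1 -0.73 ± 0.48). Fatty acid oxidation genes were lower in 24 of 26 (median -0.66, Pdk4 -1.34 ± 0.69, with Ucp2 at 1.18 ± 0.67). Muscle genes were lower in 26 of 26 (median -0.54, Xirp2 -1.09 ± 0.56, Mybpc1 -0.92 ± 0.76). The difference in mean muscle level was -0.877, which the low level of semaglutide A242 (8.85) made smaller. Combination A320 alone, at 6.289 log2 CPM against a group mean of 9.774, made up nearly all of that difference. Muscle genes took 15.05% of non-mitochondrial counts in the combination and 20.5% with semaglutide (exact permutation p = 0.286, n = 5 and 5). Combination A320, at 1.26%, made this difference larger, and the group medians were 18% and 22.07%.

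Camera called 13 lists for semaglutide plus PYY versus semaglutide. The adjusted p was 1.08e-11 for cell cycle, 8.38e-09 for oxidative phosphorylation, 4.8e-06 for fatty acid oxidation, 5.89e-06 for erythroid. Next came 7.83e-05 for osteoblast, 8.48e-05 for skeletal muscle, 0.000101 for macrophage, 0.000206 for fibroblast, 0.000448 for chondrocyte, 0.00733 for neutrophil, 0.0283 for megakaryocyte, 0.0397 for marrow stroma and 0.047 for plasma cell. The neutrophil list had an adjusted p = 0.711 with an estimated correlation and the other 12 each had 0.672, and adjusted over the list alone 1 fibroblast gene rose and no member of the other lists passed. Single genes called by edgeR numbered 0 (863 at an unadjusted p under 0.05), DESeq2 called 16 and limma voom 1. Genes of smallest p, none passing, were Cenpm (211 counts against 1, adjusted p = 0.186), Ddr2 (1.423 ± 0.303), Hebp1 (1.59 ± 0.39), Fbxo45 (-1.23 ± 0.30), the ubiquitin ligase gene Cop1 (-0.86 ± 0.24) and the pseudogene Eif4g1-ps1 (-0.86 ± 0.24). Without combination A251 the edgeR test called 3 genes, and with 2 surrogate variables 2 lists were called and none of the 13 was kept.

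Semaglutide plus PYY versus PYY asks what semaglutide added to PYY. Matrix and vessel genes were lower in the combination. The PYY libraries also serve PYY versus MetOP saline with opposite sign, so a chance high in them would show in both. Exact permutation tests of list level gave p = 0.222 for fibroblast, 0.111 for endothelial and 0.27 for osteoblast genes (n = 5 and 4). Fibroblast genes were lower in 16 of 17 (median log2 fold change -1.69, Fbn1 13.0 ± 5.42 CPM against 78.5 ± 99.5, n = 5 and 4, Col6a3 -2.21 ± 0.59). Endothelial genes were lower in 16 of 18 (median -0.78, Eng -0.99 ± 0.31, Emcn -0.95 ± 0.33). Osteoblast genes were lower in 24 of 25 (median -1.60, Col5a1 -2.42 ± 0.72, Col5a2 -1.88 ± 0.58, Col1a1 -2.14 ± 0.88). Chondrocyte genes were lower in 17 of 17 (median -2.93, Comp -3.46 ± 1.48, Epyc -4.86 ± 2.31). Osteoclast genes were lower in 17 of 20 (median -0.85, also with 1 gene at its bound, Ctsk -2.18 ± 0.82). Wnt signalling genes were lower in 16 of 20 (median -0.45, the Wnt inhibitors Wif1 -2.25 ± 0.76 and Nkd2 -1.05 ± 0.53). Ocstamp, a gene of osteoclast fusion, had 0 counts in the combination and 134 with PYY, at least 40.2-fold lower over the group. Nitric oxide genes were lower in 20 of 22 (median -0.57, Cav1 -0.96 ± 0.30, with Ddah1 at 1.05 ± 0.55). Interferon response genes were lower in 17 of 23 (median -0.40, Bst2 -0.61 ± 0.33, Oas2 -3.50 ± 1.91). Cholesterol synthesis genes were lower in 19 of 24 (median -0.28, Stard4 -2.18 ± 0.92, Insig1 -0.78 ± 0.39).

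Higher in semaglutide plus PYY versus PYY were oxidative phosphorylation genes in 38 of 38 (median 0.57, Atp5me 0.79 ± 0.44, Uqcrq 0.86 ± 0.48), muscle genes in 24 of 26 (median 0.95, Eno3 1.25 ± 0.76, Pygm 1.18 ± 0.73). Neutrophil genes were higher in 18 of 19 (median 2.10, Camp 2.60 ± 0.97, Lcn2 2.53 ± 0.99), megakaryocyte genes in 11 of 13 (median 1.41, Treml1 3.42 ± 1.16, with Vwf at -0.92 ± 0.36). Glycolysis genes were higher in 14 of 22 (median 0.49, Gpi 1.07 ± 0.50, with Pfkp at -0.91 ± 0.48). Muscle genes took 15.05% of non-mitochondrial counts in the combination and 10.25% with PYY (exact permutation p = 0.413, n = 5 and 4). Combination A320, at 1.26%, made this difference smaller and PYY A216, at 2.51%, made it larger. The group medians were 18% and 11.93%. The basement membrane genes Col15a1 (-2.05 ± 0.44) and Lamb1 (-1.48 ± 0.32) and Abi3bp (-3.38 ± 0.74) had the smallest p-values on the lower side, each at an adjusted p of 0.597. Mapkapk3 (1.00 ± 0.26), Rn5-8s (3.96 ± 1.04) and Msrb1 (1.03 ± 0.28) had those on the higher side, and none passed.

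Camera called 14 lists for semaglutide plus PYY versus PYY. The adjusted p was 1.6e-08 for oxidative phosphorylation and for fibroblast, 4.21e-08 for endothelial, 6.12e-08 for osteoblast, 3.33e-07 for skeletal muscle. Next came 1.67e-05 for neutrophil, 0.00693 for interferon response and for Wnt signalling, 0.00767 for osteoclast and for megakaryocyte, 0.011 for nitric oxide, 0.0197 for glycolysis and for chondrocyte, and 0.0401 for cholesterol synthesis. These became an adjusted p = 0.574 with an estimated correlation for 7 of the 14, among them the fibroblast, endothelial and osteoblast lists, 0.588 for muscle, 0.653 for neutrophil and 0.764 for chondrocyte genes, and 0.662 for the rest. Adjusted over the list alone, 10 fibroblast, 9 endothelial and 2 osteoblast genes fell and no member of the other 11 lists passed. By edgeR 0 genes were called (953 at an unadjusted p under 0.05), DESeq2 called 13 and limma voom 588. The edgeR test called 2 genes without PYY A220 and 1 without combination A251, and with the muscle covariate 8 lists were called.

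Semaglutide versus PYY sets the single drugs against each other, and gave the only gene that passed the edgeR test in any of the 8 comparisons. Ddr2, a receptor tyrosine kinase for fibrillar collagen (chromosome 13, 82195463 to 82317363, minus strand), fell to 6.01 ± 1.499 CPM with semaglutide (n = 5) from 32.5 ± 10.6 with PYY (n = 4). Its log2 fold change was -2.43 (SE 0.32, edgeR adjusted p = 0.0014), and the 5 semaglutide libraries, between 4.47 and 7.67 CPM, all lay below the 4 PYY libraries, between 25.95 and 48.3 CPM. In the other groups Ddr2 was at 6.20 ± 2.57 CPM in healthy controls (n = 4), 19.3 ± 6.19 in MetOP saline (n = 5) and 16.1 ± 6.28 in the combination (n = 5). Fibroblast genes were lower with semaglutide in 17 of 17 (median -2.39, Fbn1 -3.32 ± 0.59, Col6a1 -3.10 ± 0.58). Osteoblast genes were lower in 24 of 25 (median -2.58, Col5a2 -2.59 ± 0.59, Col5a1 -2.85 ± 0.73, Col1a1 -3.25 ± 0.91, Alpl -2.51 ± 0.72, Runx2 -2.04 ± 0.71). Endothelial genes were lower in 17 of 18 (median -0.98, Ptprb -1.22 ± 0.30, Sox17 -1.30 ± 0.37).

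Further lists were lower with semaglutide than with PYY. These were chondrocyte genes in 17 of 17 (median -5.58, also with 1 gene at its bound, Col11a2 -4.46 ± 1.30, Comp -5.18 ± 1.60), osteoclast genes in 19 of 20 (median -1.29, Ctsk -3.57 ± 0.86, Acp5 -3.40 ± 0.91). Macrophage genes were lower in 15 of 15 (median -0.74, Axl -1.34 ± 0.40, Cd68 -1.93 ± 0.73), cell cycle genes in 33 of 35 (median -0.82, Ccnb1 -1.29 ± 0.59, Cdt1 -1.30 ± 0.66). Wnt signalling genes were lower in 17 of 20 (median -1.08, Nkd2 -2.05 ± 0.54, Wif1 -2.69 ± 0.77) and nitric oxide genes in 17 of 22 (median -0.76, Gucy1a1 -1.46 ± 0.44, Ednrb -2.47 ± 0.86). Marrow stroma genes were lower in 10 of 13 (median -0.98, Igfbp5 -1.03 ± 0.32, Ebf3 -1.04 ± 0.41) and peptide receptor genes in 4 of 6 (median -1.31, Calcrl -1.85 ± 0.66, the leptin receptor gene Lepr -1.40 ± 0.60). Semaglutide A238 alone, with a peptide receptor level of -1.341 log2 CPM against 0.737 to 1.55 in the other semaglutide libraries, made the difference in mean level (-1.199) larger. Higher with semaglutide were oxidative phosphorylation genes in 37 of 38 (median 0.99, Uqcrh 1.01 ± 0.35, Cox5a 1.24 ± 0.45), muscle genes in 26 of 26 (median 1.40, Casq1 1.503 ± 0.683, Ryr1 1.40 ± 0.65). Fatty acid oxidation genes were higher in 23 of 26 (median 0.73, Acadm 1.07 ± 0.59, Hadha 0.85 ± 0.48), glycolysis genes in 15 of 22 (median 0.95, Hk2 1.01 ± 0.40, with Pfkp at -1.27 ± 0.49). Circadian clock genes were higher in 15 of 18 (median 0.36, Ciart 2.78 ± 0.92, Hlf 1.19 ± 0.53). PYY A216 alone, with a circadian level of 2.286 log2 CPM against 3.135 to 3.246 in the other PYY libraries, made the difference in mean level (0.477) larger. Muscle genes took 20.5% of non-mitochondrial counts with semaglutide and 10.25% with PYY (exact permutation p = 0.0476, adjusted 0.333, n = 5 and 4).

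Camera called 16 lists for semaglutide versus PYY. The adjusted p was 2.38e-17 for oxidative phosphorylation, 3.76e-11 for fibroblast, 4.53e-11 for skeletal muscle and for osteoblast, 1.37e-07 for endothelial, 6.64e-06 for fatty acid oxidation. Next came 0.00035 for cell cycle, 0.000369 for chondrocyte, 0.00117 for osteoclast, 0.00195 for macrophage, 0.00216 for nitric oxide, 0.0065 for Wnt signalling, 0.0141 for circadian clock, 0.0146 for glycolysis, 0.016 for marrow stroma and 0.0324 for peptide receptors. The first 5 and nitric oxide, Wnt signalling and peptide receptors each had an adjusted p = 0.384 with an estimated correlation, with 0.424 for glycolysis and marrow stroma, 0.467 for fatty acid oxidation, 0.505 for chondrocyte and 0.583 for cell cycle. The osteoclast, macrophage and circadian lists had 0.475. Adjusted over the list alone, 21 osteoblast genes fell and 1 rose, 16 chondrocyte, 15 fibroblast, 14 endothelial, 4 osteoclast, 2 Wnt, 1 macrophage and 1 marrow stroma gene fell, and no member of the other 8 lists passed. The number of called genes depended on single libraries and on the tool. It was 1 of 15271 (2575 at an unadjusted p under 0.05), but 1021 without PYY A220, 164 without combination A251, 48 without combination A320 and 3 without semaglutide A242, and DESeq2 called 502 and limma voom 3809. With 2 surrogate variables 5 of the 16 lists were kept, and the cell cycle list was called in the opposite direction (median 0.163, adjusted p = 0.0162).

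The interaction of semaglutide and PYY asks whether the combination departed from the sum of both log2 effects. Marrow lists were higher in the combination than that sum. The semaglutide and PYY libraries enter the interaction with negative sign, so a chance low in them would also raise it. Cell cycle genes were higher in 35 of 35 (median log2 interaction 1.78, Mcm4 1.95 ± 0.59, Rrm1 1.41 ± 0.44). Erythroid genes were higher in 21 of 21 (median 2.12, Gata1 2.47 ± 0.88, Slc25a37 2.21 ± 0.91). Neutrophil genes were higher in 19 of 19 (median 2.17, Camp 3.01 ± 1.27, Np4 2.21 ± 1.04). Megakaryocyte genes were higher in 12 of 13 (median 2.32, Treml1 4.39 ± 1.49, Clec1b 2.54 ± 0.91). Macrophage genes were higher in 13 of 15 (median 1.44, Hmox1 1.89 ± 0.81, Spic 2.41 ± 1.04). Chondrocyte genes were higher in 17 of 17 (median 2.96, Ucma 4.60 ± 2.41, Snorc 4.06 ± 2.97). Osteoblast genes were higher in 19 of 25 (median 0.83, Dlx5 1.51 ± 1.07, Runx2 1.35 ± 0.97). Osteoclast genes were higher in 14 of 20 (median 0.47, with Nfatc1 in the other direction at -0.99 ± 0.33). Endothelial genes were lower in 15 of 18 (median -0.65, Robo4 -1.48 ± 0.49, Kdr -0.97 ± 0.43). Fatty acid oxidation genes were lower in 23 of 26 (median -0.80, Pdk4 -1.74 ± 0.98, with Ucp2 at 1.78 ± 0.98). Interferon response genes were lower in 18 of 23 (median -0.48, Rtp4 -2.56 ± 0.82, Usp18 -2.16 ± 0.99). The osteocyte gene Dmp1 had an interaction of 2.24 (SE 0.76) and Col1a1 one of 0.83 (SE 1.19).

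For the interaction of semaglutide and PYY camera called 11 lists. The adjusted p was 4.43e-19 for cell cycle, 4.87e-13 for erythroid, 1.59e-09 for neutrophil, 2.62e-05 for megakaryocyte, 4.26e-05 for chondrocyte and for macrophage. Next came 0.0011 for endothelial, 0.00383 for fatty acid oxidation, 0.00991 for interferon response, 0.0117 for osteoblast and 0.0186 for osteoclast. The first 4 had an adjusted p = 0.733 with an estimated correlation, the osteoblast list 0.778 and the others 0.756, and 0 members of the 11 lists passed adjusted over the list alone. Gene by gene, edgeR called 0 (700 at an unadjusted p under 0.05), DESeq2 called 3 and limma voom 0. Genes of smallest p besides Cenpm (adjusted p = 0.0973, with 1 count in the semaglutide group) were Igf2r (-1.13 ± 0.30), Spen (-1.63 ± 0.41), the laminin gene Lamc1 (-1.39 ± 0.37) and the ribosomal pseudogenes Rpl38-ps9 (1.18 ± 0.29) and Rps21-ps1 (1.86 ± 0.51), and none passed.

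Whether the drugs turned back the changes of the disease model was asked from fold changes across genes, which are not independent replicates. The contrasts share the MetOP saline libraries, which alone give a negative correlation. For the disease and semaglutide contrasts the correlation was -0.439 (covariance -0.586), against -0.461 (covariance -0.402) in simulated unchanged groups, and -0.0404 when different saline libraries served each contrast. The values were -0.31 (covariance -0.329) against -0.433 (-0.405) and 0.0579 for PYY, and -0.428 (-0.485) against -0.463 (-0.405) and -0.0048 for the combination. The edgeR test called 0 genes in both contrasts of any pair (its calls give an expected overlap of 0). DESeq2 called Ddr2 and RGD1562420 higher in the disease model and lower with semaglutide, 2 genes against 0.21 from independent lists, Klkb1 changed back with PYY (1 against 0.003) and the Y-linked Kdm5d with the combination (1 against 0.0075). Independent lists take no account of the shared saline libraries, which favour opposite calls. The DESeq2 calls are therefore not shown to exceed chance. Except for Ddr2 these calls rested on 1 to 3 libraries, since RGD1562420 had over 9 counts only in MetOP saline A226 and A229, Klkb1 was counted only in control A387 and A392 and PYY A215, and Kdm5d only in control A387 and combination A248 and A318. RGD1562420, Klkb1 and Kdm5d were named after their values were seen.

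The responses to the drugs were set side by side in the same way. Semaglutide and combination fold changes correlated across genes at 0.579 (covariance 0.622), against 0.505 (0.408) in simulated unchanged groups, and at 0.0952 with different saline libraries in each contrast. Semaglutide and PYY gave 0.373 (0.376) against 0.469 (0.405) and -0.0133, and PYY and the combination 0.467 (0.399) against 0.47 (0.407) and 0.00994. Neither edgeR nor DESeq2 called a gene in both of any such pair, where independent lists of the DESeq2 calls give at most 0.014 in the same direction and 0.017 in opposite directions.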

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

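The tests in this section were chosen after the patterns they address were seen, except the skeletal muscle covariate, and what each explanation predicts was written before its test was run, except for that of X-linked relatives.

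Lower osteoblast, osteoclast and chondrocyte lists in semaglutide versus MetOP saline may reflect the tissue taken up with each femur. More muscle in the sample alone is argued against as the whole cause, since the osteoblast median was -1.70 with the muscle covariate and -2.05 without it (-2.03 to -1.448 with the covariate and each library left out, the highest without MetOP saline A224). A varying share of bone surface and growth plate could also produce it, and the deviations of the osteoblast and osteoclast lists from their group means correlated at 0.88 over the 23 libraries, so this stays open. With 2 surrogate variables in semaglutide versus MetOP saline the osteoblast median was -0.50 (adjusted p = 0.00187), so most of the difference lies along variation that such a fit removes, whether it comes from treatment or sampling. An effect of semaglutide on bone cells and a difference in sampled tissue could not be told apart here.

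Y-linked transcripts (Eif2s3y, Ddx3, Kdm5d and Uty, chosen after their values were seen) appeared in libraries labelled female, with 1623 counts over the 4 genes in combination A248, 638 in A318, 87 in A251 and 24 in A320, and 45 and 9 in control A387 and A389. Reads of X-linked relatives cannot be the source, since 17 libraries had no count over the 4 Y-linked genes that have an X-linked relative, and 16 of these had as many X-linked counts as A248. A male animal in place of the labelled one could not be told, because 0 genes of the table are named Xist. A small share of male RNA or of reads from another library may also explain them, but the summed ratio to the X-linked relatives was 0.497 in A248 and 0.136 in A318, and by gene 1.11 for Eif2s3y, 1.97 for Kdm5d, 0.95 for Uty and 0.212 for Ddx3 in A248 (0.373, 0.547, 0.227 and 0.0419 in A318), so 3 of the 4 ratios go against a small share in A248 while A318 stays open. Without A248 and A318 the lists kept were 3 of 6 in semaglutide plus PYY versus MetOP saline, 11 of 13 versus semaglutide, 12 of 14 versus PYY and 8 of 11 in the interaction.

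Of 10816 genes with a mean count over 50, between 4 and 282 had no count in a library. Counting error alone gives 9.53e-11% of the 1520 zeros, if each gene keeps the same share of counts in every library. Choosing genes with a mean count over 50 made that value small in advance, and the makeup of the libraries varied. A part played by low depth is therefore not excluded for these zeros. Few RNA molecules behind a library might produce them, and the percentage of mitochondrial counts correlated with the number of such genes (Spearman rho = 0.474, permutation p = 0.0234, n = 23), which does not tell it from RNA loss of another kind.

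Single libraries stood apart from their group in 10 of 195 values tested, against 9.75 from chance at about 1 in 20. Semaglutide A238 had 155 abundant genes at 0 (12 to 52 in the others) and a peptide receptor level of -1.341 (0.737 to 1.55). Semaglutide A242 had a skeletal muscle level of 8.85 (10.864 to 11.351) and an osteocyte level of 1.327 (-0.06 to 0.304). PYY A220 had 37.25 M counts (22.53 to 24.81), and PYY A216 a circadian level of 2.286 (3.135 to 3.246). The B-cell level was -1.45 in MetOP saline A265 (1.096 to 1.913) and the T and NK cell level 0.895 in combination A320 (-2.173 to -1.629). The chondrocyte level was 5.815 in control A392 (-2.077 to -0.753) and the unfolded protein level 3.709 in control A389 (3.936 to 3.943).

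Interaction medians were 1.779 for cell cycle, 2.116 for erythroid, 2.171 for neutrophil, 2.32 for megakaryocyte, 2.957 for chondrocyte and 1.438 for macrophage genes. They were 0.833 for osteoblast, 0.472 for osteoclast, -0.653 for endothelial, -0.796 for fatty acid oxidation and -0.48 for interferon response genes.

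Whether chance could give as many differences was asked with 100 splits of the samples per comparison, the real grouping among them and counted in each number below. Genes at an unadjusted p under 0.05 were as many in 2 splits for MetOP saline versus healthy control (1000, highest other 1122), 2 for semaglutide versus MetOP saline (1744, highest other 1947) and 4 for semaglutide versus PYY (2575, highest other 3665). They were as many in 23 for PYY versus MetOP saline (740, highest other 1908) and 80 for semaglutide plus PYY versus MetOP saline (468, highest other 2397). The number was 37 for semaglutide plus PYY versus semaglutide (863, highest other 3477). It was 33 for semaglutide plus PYY versus PYY (953, highest other 4732) and 38 for the interaction (700, highest other 3438). Chance is not excluded in these 5. The lower numbers, 2, 2 and 4, were not adjusted for the number of comparisons, so they do not exclude chance either. The 1 gene called in semaglutide versus PYY was matched or exceeded in 3 splits, the real grouping and 2 others (highest other 357).

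Called lists were as many in 34 of 100 splits for MetOP saline versus healthy control (8, highest other 16), 26 for semaglutide versus MetOP saline (12, highest other 18), 56 for PYY versus MetOP saline (11, highest other 20) and 90 for semaglutide plus PYY versus MetOP saline (6, highest other 19). They were as many in 46 for semaglutide plus PYY versus semaglutide (13, highest other 22), 44 for semaglutide plus PYY versus PYY (14, highest other 22), 35 for semaglutide versus PYY (16, highest other 23) and 66 for the interaction (11, highest other 20). Chance is therefore excluded for no number of called lists. Some splits called up to 706, 2403 and 451 genes in semaglutide plus PYY versus semaglutide, semaglutide plus PYY versus PYY and the interaction. What those splits have in common was not tested.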

How the results depend on the processing

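The tests with other tools, filters and normalizations were fixed before the data were examined, and those without mitochondrially encoded genes, without libraries high in Y-linked or mitochondrial counts and with 2 surrogate variables were chosen after results were seen. No paired analysis was possible because the groups share no replicate numbers. In the order MetOP saline versus healthy control, semaglutide, PYY and semaglutide plus PYY versus MetOP saline, semaglutide plus PYY versus semaglutide and versus PYY, semaglutide versus PYY and interaction, edgeR called 0, 0, 0, 0, 0, 0, 1 and 0 genes and DESeq2 51, 92, 5, 5, 16, 13, 502 and 3. With limma voom and sample weights 184 genes were called for semaglutide versus MetOP saline, 39 for PYY versus MetOP saline, 1 for semaglutide plus PYY versus semaglutide, 588 for semaglutide plus PYY versus PYY and 3809 for semaglutide versus PYY. Without the 3 libraries numbered apart 5 genes were called for semaglutide plus PYY versus PYY and 59 for semaglutide versus PYY, and with 2 surrogate variables 1 for PYY versus MetOP saline. Leaving out each library gave 0 to 1 genes for PYY versus MetOP saline, 0 to 3 for semaglutide plus PYY versus semaglutide, 0 to 2 for semaglutide plus PYY versus PYY and 1 to 1021 for semaglutide versus PYY, and 0 to 0 in the other 4. The 8, 12, 11, 6, 13, 14, 16 and 11 gene lists called in the 8 comparisons became 0, 0, 0, 0, 0, 0, 0 and 0 both with an estimated correlation and with the directional test of fry. With the skeletal muscle covariate 3 lists were called in MetOP saline versus healthy control and 8 in semaglutide plus PYY versus PYY, and 3, 9, 6, 6, 8, 5, 7 and 10 of the called lists were kept. Without the 3 libraries numbered apart 5 lists were called in MetOP saline versus healthy control and 14 in semaglutide plus PYY versus MetOP saline. With 2 surrogate variables the lists were 3 in MetOP saline versus healthy control, 2 in semaglutide plus PYY versus semaglutide and 10 in semaglutide versus PYY. Leaving out each library gave 0 to 9, 11 to 15, 10 to 17, 3 to 15, 10 to 17, 11 to 17, 15 to 18 and 8 to 15 lists. Genes of the disease contrast changed back numbered 2 for semaglutide, 1 for PYY and 1 for semaglutide plus PYY with DESeq2, and 0 with edgeR. Of 11797 results for named genes in other fits, 166 passed where they had not, and since only Ddr2 passed in edgeR these results could hardly weaken or reverse and say little about stability. The cause of these differences was not tested.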

Other observations

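All tests of relations below were chosen after the list results were seen.

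Genes of dividing cells and of red cell precursors varied together in these femora. Cell cycle and erythroid levels correlated at 0.943 over the 23 libraries (Spearman rho = 0.944, permutation p = 1e-05, 6 relations in the family) and at 0.929 within groups. Osteoblast and osteoclast levels, of cells that form and resorb bone, correlated at 0.891 (rho = 0.848, permutation p = 1e-05). Without the 2 libraries farthest from the median osteoblast level (combination A251 and PYY A216) the value was 0.841. Osteoblast levels also followed chondrocyte levels (r = 0.659, permutation p = 0.00084) and ran against skeletal muscle levels (r = -0.5, permutation p = 0.0144), the latter at -0.276 without combination A251 and PYY A216. Non-mitochondrial counts and the number of abundant genes at 0 gave r = -0.473 (permutation p = 0.0273), rho = -0.414 (permutation p = 0.0515) and r = -0.36 without PYY A220 and MetOP saline A229.

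Camera called 11 of the 34 lists in no comparison. Closest were mast cell and basophil genes, higher in 9 of 10 in the interaction (median 1.97, adjusted p = 0.0533), and genes of the IGF axis, higher in 9 of 14 for PYY versus MetOP saline (median 0.385, adjusted p = 0.0574). Osteocyte genes were lower in 11 of 14 for semaglutide versus PYY (median -0.888, adjusted p = 0.0819). Inflammatory genes were lower in 10 of 17 for semaglutide plus PYY versus PYY (median -0.293, adjusted p = 0.0843). For B cells the smallest adjusted p was 0.138, for glucocorticoid response 0.144, for hypoxia 0.3 and for T and NK cells 0.428. It was 0.454 for adipocyte genes, 0.565 for fatty acid synthesis and 0.753 for the unfolded protein response.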
